A study of Mus musculus with 3 samples.

How the data were processed

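RNA bound to EGFP-tagged ribosomes was immunopurified from the deep cerebellar nuclei of Htr6-TRAP mice with anti-EGFP antibodies on magnetic beads and purified with a commercial kit, per the labels' protocols. There are 3 libraries, all of 1 group, numbered as replicates 1 to 3 in their titles. The deposited values are raw counts of reads per gene, whole numbers with 1 table per library and 32531 gene symbols in each. The submitters' processing notes name STAR 2.0.0e, HTSeq and the build mm10. The gene annotation, the strand setting and the kit for amplification and library preparation are not given in the sources used here. The files' summary rows are those that HTSeq writes, and they were left out of library sizes and of every test, as was a row named unknown that held 0 counts. In replicates 1, 2 and 3, 50.2%, 44.1% and 44.7% of the counted reads were assigned to no annotated feature, and 1.77%, 1.94% and 1.88% to several genes. Counted reads here are those assigned to a gene, to several genes or to no feature. Since the annotation and counting settings are not given, reads without a feature may include reads in introns or on the other strand of a gene. Multiply aligned reads (5263183, 4434540 and 3710157) were not counted to genes, which lowers the counts of genes with near-identical copies. The files list no mitochondrially encoded gene. Without strand information, overlapping antisense genes cannot be told apart.

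From these counts, CPM values were computed with library sizes scaled by the TMM method of edgeR 4.0.16 in R 4.3.3, and log values are log2(CPM + 1), with a pseudocount of 1, which understates folds of low genes. CPM is not scaled by gene length, so a long gene takes more counts than a short gene with as many molecules; RPKM, with exon lengths from the GENCODE release M21 annotation of the same build matched by symbol (23155 symbols), was an alternative. Gene coordinates are from that annotation. Depth was 7622010 to 8842058 gene counts per library. Reads are not independent molecules where no molecular identifiers are given, so limits from a count of 0 (3 counts) cover counting error only.

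The labels give 1 group, so no test between groups was made. Before the data were examined, 26 gene lists with 303 genes, 8 differences between list medians, 6 differences between genes and the rule for naming genes were fixed; 2 of the listed genes (both haemoglobin genes) are not among the rows analysed here. Named genes are Htr6 and Rpl10a, the genes of the fixed pairs, up to 5 members of highest and 3 of lowest mean CPM in each list, the 20 genes of highest mean CPM outside ribosomal protein genes, and the members of lists that deviated in 1 library; 1 of these 20 has only a clone identifier as its symbol and is not named. Some genes that this rule names are not reported here, though they count in their lists. A few further members are named with their values to complete a group. Differences within a library are given as mean ± SD over 3 libraries with an exact two-sided sign-flip permutation test (scipy 1.17.1), of which 14 were computed; none can pass a threshold of 0.05, so no adjusted values are given. Each list's median was placed among 10000 random lists of the same size drawn from the 14036 genes with at least 10 counts summed over the libraries, as a description. Lists that hold genes under that minimum are placed low by construction, so only high percentiles are reported.

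Spread between libraries was tested on the counts of genes with at least 10 counts in 2 libraries, by a Poisson chi-square test with TMM offsets and by edgeR's quasi-likelihood dispersion (glmQLFit, intercept only) of each gene over its trended prior, against an F distribution, both with Benjamini-Hochberg adjustment. Deviations of a list in a library used members with a mean of at least 10 counts and random lists matched in 20 expression bins. The tests were checked on simulated data of 11168 genes: the Poisson test recovered 86% of genes changed 2-fold in 1 library and 100% of those changed 4-fold, with 16 calls among unchanged genes. Alternatives were DESeq2 1.42.0 size factors, a pseudocount of 0.1, RPKM, means over list members, filters on counts, robust estimation in edgeR, limma 3.58.1 and leaving out each library.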

Results

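Translating ribosome affinity purification (TRAP) followed by RNA sequencing was used to profile neurons of the deep cerebellar nuclei, the output nuclei of the cerebellum, in adult mice. The mouse line, Htr6-TRAP NIDA113 on a C57BL/6J background, carries the ribosomal protein L10a fused to EGFP under the name of the serotonin receptor gene Htr6. Ribosomes that hold the tagged protein are pulled down with anti-EGFP antibodies, and the RNA bound to them is sequenced. All 3 libraries are immunopurified samples of a single group, so the comparisons below are between genes and gene groups within a library, with the spread between the 3 libraries as the error. Unpurified tissue RNA was not analysed here, so a level is an abundance in the purified RNA and not an enrichment over the tissue. The libraries held 7695397, 8842058 and 7622010 counts assigned to genes in replicates 1, 2 and 3. At least 1 count fell on 13095, 13586 and 13951 genes. A count of 0 in a library allows a level of up to 0.397, 0.341 and 0.385 CPM (gene counts scaled to the effective library size), taking 3 counts as the limit and considering counting error only. The labels do not say whether the libraries came from separate animals or pools, so the spread may be partly technical. Xist, which female mice transcribe, and the Y-linked gene Ddx3y were both counted in every library, which 1 animal alone does not give. Values are mean CPM ± SD over n = 3 libraries unless stated otherwise.

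Few reads were counted to Htr6, the gene the line is named for. Htr6 (ENSMUSG00000028747.10, minus strand of chromosome 4, positions 139061108 to 139075570 in mm10, 4 exons in its longest coding transcript) had 0, 7 and 0 counts in replicates 1, 2 and 3, or 0.265 ± 0.459 CPM (SD, n = 3). The gene models used for the deposited counts are not given in the sources used here, so these counts cover Htr6 only as far as its model did. Rpl10a, the gene of the tagged ribosomal protein (ENSMUSG00000037805.15, plus strand of chromosome 17, positions 28328471 to 28331033), had 641, 553 and 774 counts, or 82.3 ± 18.4 CPM. Rpl10a ranked 6th of 84 cytosolic ribosomal protein genes, picked by symbol, which can take in like-named paralogs. It exceeded the median of the 83 others by 2.12 ± 0.38 on the log2(CPM + 1) scale (4.33-fold, higher in 3 of 3 libraries). Counts per gene do not separate reads of the transgene from those of the endogenous Rpl10a, and 78.8% of the Rpl10a transcript is near-identical to 1 other annotated gene. Of the 14 serotonin receptor genes, Htr5a (27.2 ± 5.7 CPM) and Htr2c (25.2 ± 24.1 CPM) were the highest, followed by Htr1b (4.8 ± 5.1 CPM), Htr1d and Htr2a. Only Htr5a, Htr2c and Htr1b had at least 3 counts in every library, while Htr3a and Htr3b, subunits of the serotonin-gated ion channel, had no count in any. The difference of Htr6 minus Htr5a was -4.52 ± 0.59 on the log2(CPM + 1) scale, with Htr6 lower in 3 of 3 libraries. Since Htr6 was at 0 in 2 of them, the size depends on the scale, and it was -7.02 with a pseudocount of 0.1 and -2.45 as RPKM. For this and every other difference within a library, the exact two-sided sign-flip permutation test over 3 libraries cannot give a p below 0.25. That value was reached for every difference of 1 sign in all 3 libraries, so sizes are judged below against the SD.

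The most abundant transcripts were those of neurons. Snap25, a protein of the synaptic vesicle fusion machinery, reached 14585 ± 2875 CPM (SD, n = 3). Among the 20 most abundant genes were the cytoskeletal genes Map1b (10384 ± 723 CPM), Tubb4a (6402 ± 659 CPM) and Nefm (3404 ± 825 CPM). The calcium sensor gene Vsnl1 (4536 ± 648 CPM), the presynaptic scaffold gene Pclo (3042 ± 341 CPM) and the axonal ankyrin gene Ank2 (3093 ± 286 CPM) were there too. Others in this group were Cdr1 (5809 ± 1239 CPM), the mitochondrial ATP synthase gene Atp5b (3844 ± 277 CPM), Itpr1, Clip3, Srrm2, Ndrg4, Prrc2c and the axonal motor gene Kif1a (2613 ± 311 CPM). The ribosomal RNA precursor row Rn45s (23063 ± 1236 CPM) and the nuclear noncoding RNA Malat1 (12505 ± 2091 CPM) also ranked among them. All 12 pan-neuronal genes had at least 10 CPM and 11 of them at least 100 CPM, from Snap25 and the neurofilament genes Nefm, Nefl and Nefh down to Tubb3 at 42.9 ± 15.3 CPM. Rbfox3, which encodes the neuronal nuclear antigen NeuN, was at 223 ± 40.5 CPM and the synaptic vesicle gene Syp at 652 ± 153 CPM. The list median, 9.01 ± 0.06 on the log2(CPM + 1) scale, was above that of all 10000 random lists of expressed genes.

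Markers of both excitatory and inhibitory transmission were present in the purified RNA. Slc17a6, the vesicular glutamate transporter VGLUT2 used by glutamatergic neurons of the deep nuclei (plus strand of chromosome 7, positions 51622006 to 51671119), was at 302 ± 80.2 CPM (SD, n = 3). It exceeded Slc17a7, the VGLUT1 gene used by granule cells (54.7 ± 18.5 CPM), by 2.46 ± 0.72 on the log2(CPM + 1) scale, and it was higher in 3 of 3 libraries. Both genes of the enzyme that makes GABA were abundant, Gad2 at 414 ± 169 CPM and Gad1 at 203 ± 60.4 CPM, with Gad1 lower by a log2 difference of -0.99 ± 0.32 in 3 of 3 libraries. In contrast, the vesicular inhibitory transporter gene Slc32a1 had 324, 33 and 190 counts (23.7 ± 19.6 CPM), and Slc6a5, the glycine transporter of glycinergic neurons, had 158, 58 and 341 counts (23.8 ± 18.7 CPM). Slc17a6 exceeded Slc32a1 by 4.09 ± 1.46 in log2 units in 3 of 3 libraries, and by 3.25 without replicate 2, the library with the fewest Slc32a1 counts. The log2 difference of Slc32a1 minus Slc6a5, -0.16 ± 1.01, was smaller than its SD and had no common sign (exact sign-flip permutation p = 1.0). It was 0.94 as RPKM, 0.09 without replicate 2 and 0.16 without replicate 3.

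**Figure D1:**
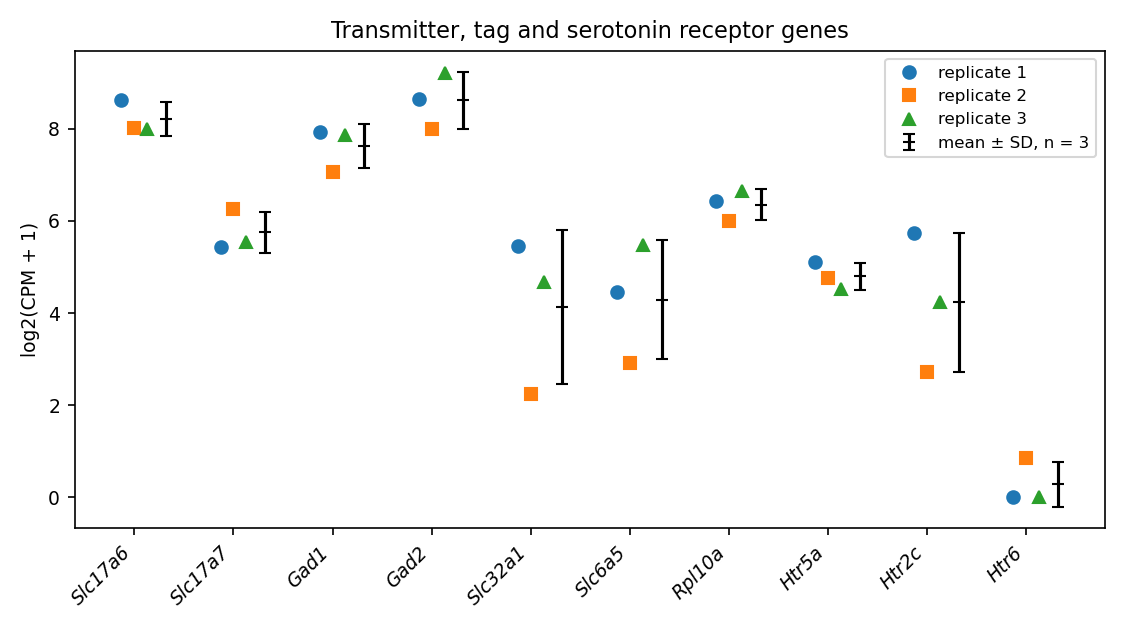
Levels of transmitter, tag and serotonin receptor genes in the 3 TRAP libraries, on a log2(CPM + 1) scale. Coloured symbols are single libraries, and black bars are the mean ± SD of n = 3. Slc17a6, Gad1 and Gad2 lie far above Htr6, which has counts in replicate 2 only.

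Genes that mark glutamatergic projection neurons of the deep nuclei were unevenly represented. Spp1 (1008, 1361 and 757 counts), Meis2 (73.2 ± 46.9 CPM; SD, n = 3) and Meis1 (58.2 ± 13.2 CPM) were clearly detected besides Slc17a6. The transcription factor genes Tbr1 (11, 154 and 96 counts) and Lhx9 (50, 73 and 29 counts) were low, Lhx2 and Lmx1a each had no count in 1 library, and Lmx1b had none in any. Of the inhibitory markers, the transcription factor gene Pax2 was at 27.7 ± 24.6 CPM, and Sox14, known from inhibitory neurons that project to the inferior olive, had no count in any library. The median of the 9 glutamatergic markers, 3.62 ± 0.65 on the log2(CPM + 1) scale, and that of the 7 GABAergic and glycinergic markers, 4.87 ± 1.35, differed by -1.24 ± 1.86. That difference was within its SD, had the glutamatergic list higher in 1 of 3 libraries (exact sign-flip permutation p = 0.5) and was -2.31 without replicate 2, -0.60 without replicate 1 and -0.82 without replicate 3. All 12 Hox genes of the caudal hindbrain, which neurons of the cerebellum do not use and those of the neighbouring hindbrain do, had 0 counts in all 3 libraries. The glutamatergic list median exceeded theirs by 3.62 ± 0.65 in log2 units in 3 of 3 libraries, a size set by the pseudocount (6.83 with a pseudocount of 0.1, 1.80 as RPKM). Of all 39 Hox genes in the files, 1 had any count, Hoxd13 with 2 counts, a gene named after its values were seen.

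Markers of neurons of the cerebellar cortex were also abundant in these libraries. All 12 granule cell markers had at least 10 CPM and 10 of them at least 100 CPM, among them Cbln3 (1077 ± 170 CPM; SD, n = 3), Fat2 (746 ± 61.0 CPM), Cbln1 (542 ± 93.7 CPM), Zic1 (540 ± 158 CPM) and Etv1 (2895, 4772 and 4962 counts). The lowest granule cell markers were Zic2, Pax6 and Slc17a7. Their list median was 8.55 ± 0.23 on the log2(CPM + 1) scale. The difference of the glutamatergic deep nuclei list minus this list was -4.93 ± 0.58, with the granule cell list higher in 3 of 3 libraries. Of 13 Purkinje cell markers, 10 had at least 10 CPM, among them Itpr1 (3669 ± 451 CPM), Rgs8 (1733 ± 502 CPM), Car8 (1154 ± 246 CPM) and Dner (463 ± 147 CPM). Other Purkinje markers were far lower, with Pcp2 at 27.6 ± 12.8 CPM, Skor2 at 7.3 ± 5.0 CPM, Gng13 at 4.0 ± 3.9 CPM and Pcp4 at 5, 2 and 1 counts. The Purkinje list median was 6.01 ± 0.23, and the glutamatergic deep nuclei list minus this list gave -2.39 ± 0.71, lower in 3 of 3 libraries, or -4.96 among members with a coding transcript of at least 2 kb. Among markers of molecular layer interneurons and Golgi cells, Kit (175 ± 19.9 CPM), Tfap2b (145 ± 84.9 CPM) and Lgi2 (42.1 ± 21.6 CPM) led, while Grm2 and Lypd6 lay under 10 CPM. The list of unipolar brush cell markers was led by Plcb4 (1029 ± 304 CPM), also used by Purkinje cells, whereas Eomes, the most specific member, had 43, 56 and 242 counts. Several of these genes are used by more than 1 type of neuron. The deep nuclei list holds mostly transcription factor genes, while the other lists mix such genes with structural and signalling genes. The list medians therefore compare these genes and not cell numbers. The class of gene alone does not account for the granule cell difference. The transcription factor genes Zic1, Etv1, Neurod1, Zic2 and Pax6 of that list had mean CPM of 540, 521, 316, 113 and 83.9. Meis2, the highest transcription factor gene of the deep nuclei list, was at 73.2 CPM.

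**Figure D2:**
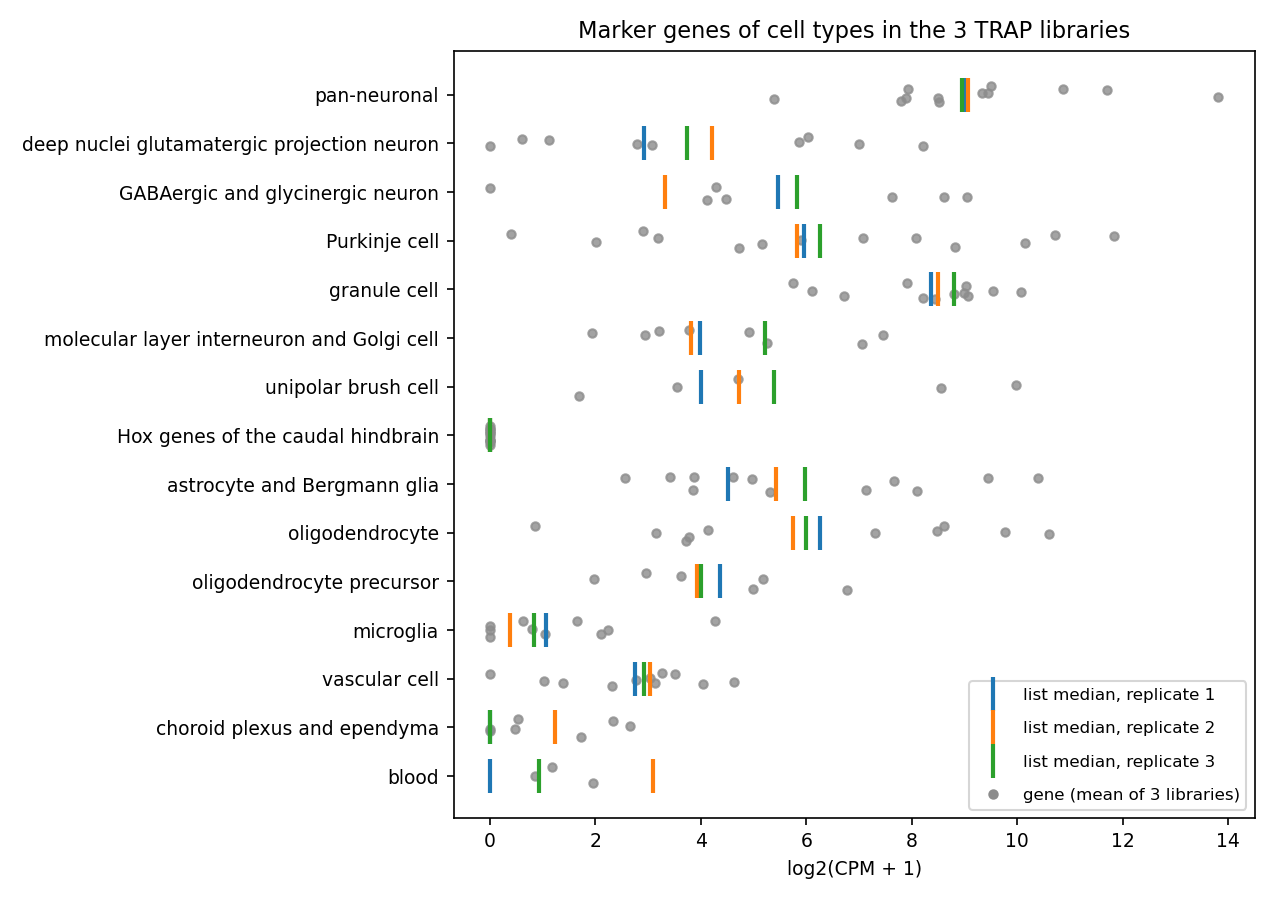
Expression of marker genes of 15 cell type lists on a log2(CPM + 1) scale. Each grey point is 1 gene (mean of 3 libraries), and each coloured tick is the median of the list in 1 library; the pan-neuronal and granule cell medians are the highest, and the Hox genes lie at 0.

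Glial, microglial and vascular lists had lower medians than the pan-neuronal list, with the largest differences for microglial and vascular markers. The medians of the oligodendrocyte list (6.00 ± 0.25 on the log2(CPM + 1) scale) and of the astrocyte list (5.31 ± 0.75) were above that of the glutamatergic deep nuclei list. Oligodendrocyte markers included the myelin genes Mbp (879 ± 153 CPM; SD, n = 3), Mobp (391 ± 51.5 CPM) and Cnp (366 ± 103 CPM), and the list median lay 2.75, 3.31 and 2.95 log2 units below that of the pan-neuronal list in replicates 1, 2 and 3 (SD 0.29). Among members with a coding transcript of at least 2 kb, that difference was 0.87 ± 0.24. Astrocyte and Bergmann glia markers were led by the glutamate transporter gene Slc1a2 (1342 ± 169 CPM), Aldoc (697 ± 67.5 CPM), which Purkinje cells also express, and Aqp4 (273 ± 35.9 CPM), and their median lay 3.70 ± 0.77 below the neuronal one. Gfap was at 31.0 ± 7.1 CPM and Aldh1l1 at 5.2 ± 2.3 CPM. Markers of oligodendrocyte precursors ranged from Vcan (121 ± 68.5 CPM) and Pdgfra (37.8 ± 28.9 CPM) to Cspg4 (5.3 ± 7.0 CPM). Microglial markers were low: Csf1r was at 19.6 ± 9.8 CPM, 4 of 10 members had at least 3 counts in every library, and C1qa, Aif1 and Trem2 had no count. The list median lay 8.25 ± 0.40 below the neuronal one. The genes without counts are short (1040, 875 and 1088 bases). Among members with a coding transcript of at least 2 kb, 4 of them microglial, the difference was 7.07 ± 0.77. In the full lists, vascular markers lay 6.11 ± 0.13 below the neuronal median, with Flt1 (32.1 ± 22.5 CPM) and Rgs5 (23.6 ± 21.9 CPM) the highest and Cldn5 at 0 counts. Each of these 4 differences had 1 sign in 3 of 3 libraries. Markers of choroid plexus and ependyma were all under 10 CPM, with Ttr at 0, 18 and 0 counts and Folr1 and Aqp1 at 0. The 3 blood genes in the files, Alas2, Hbb-bs and Hba-a2, had 9, 106 and 8 counts, 0, 66 and 3 counts, and 0, 19 and 7 counts in replicates 1, 2 and 3.

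Ion channel genes of fast-spiking and rebound-firing neurons had the highest median of the receptor, channel and transmitter lists. All 21 genes of this list, which also holds the calcium-binding protein gene Pvalb (75.4 ± 22.9 CPM), had at least 10 CPM and 11 had at least 100 CPM, including the sodium channel genes Scn8a (1987 ± 677 CPM; SD, n = 3) and Scn1a (589 ± 106 CPM). The potassium channel genes Kcna2 (1638 ± 124 CPM), Kcna1 (855 ± 53.8 CPM) and Kcnc1 (565 ± 30.4 CPM) were also high. The T-type calcium channel genes differed in level and in reproducibility, with Cacna1g at 96.4 ± 30.8 CPM while Cacna1h (25, 37 and 446 counts) and Cacna1i (6, 280 and 234 counts) varied more than 10 times over. The list median was above that of all random lists, both as CPM and as RPKM, as it was for the pan-neuronal list and the granule cell list, and those of Purkinje cell, oligodendrocyte and noncoding RNA lists were above the 95th percentile. AMPA receptor genes Gria3 (594 ± 45.5 CPM), Gria4 (403 ± 49.3 CPM) and Gria2 (254 ± 24.1 CPM) and the NMDA receptor gene Grin1 (220.0 ± 42.5 CPM) led the ionotropic glutamate receptors. Grin2b (14.6 ± 10.8 CPM) and Grin2a (8.3 ± 8.0 CPM) were low, and Grid1 and Grik4 were the lowest. For inhibition, the GABA-A receptor gene Gabrb2 (536 ± 45.5 CPM) and the glycine receptor gene Glrb (251 ± 21.6 CPM) were among the 4 of 17 subunit genes with at least 100 CPM. Glra1, the adult glycine receptor alpha subunit, was at 26.7 ± 7.0 CPM, and Gabre had no count.

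Receptors and enzymes of the modulatory transmitters were mostly low. The cannabinoid receptor gene Cnr1 was the exception among 23 receptor genes at 184 ± 32.4 CPM (SD, n = 3). The mu opioid receptor gene Oprm1 had 990, 207 and 40 counts, the kappa receptor gene Oprk1 had 9, 243 and 48, and the adrenergic receptor gene Adra1a had 243, 122 and 11. The dopamine receptor genes Drd3 and Drd4 had no count, as had Adra2b, Chrm4 and Chrm5. Nicotinic subunits were represented by Chrna4 (107 ± 68.5 CPM) and Chrnb2 (48.2 ± 19.0 CPM), which form the main brain nicotinic receptor, while 6 of 11 subunits had no count in any library. Genes for making and packaging monoamines and acetylcholine were low, with the vesicular monoamine transporter Slc18a2 at 16.6 ± 7.5 CPM, the choline transporter Slc5a7 at 223, 0 and 92 counts, and Slc6a2, Th and Dbh lower. The dopamine transporter gene Slc6a3, the serotonin synthesis gene Tph2 and Slc18a3 had no count. Of 27 neuropeptide genes, 14 had no count in any library, and Sst (138 ± 134 CPM), Cck (87.0 ± 87.4 CPM) and Penk (66.4 ± 10.2 CPM) were the only ones at 10 CPM or more. Most of the 14 have coding transcripts under 2 kb, such as Nmb (705 bases) and Pmch (749 bases), but so have Sst (721 bases) and Cck (799 bases). A loss of short transcripts stays open, so counts of 0 do not show that these genes are silent.

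The 3 libraries differed from each other far more than counting error allows. Of 11168 genes with at least 10 counts in 2 or more libraries, 10773 varied beyond Poisson counting error (chi-square test of the counts, Benjamini-Hochberg adjusted p under 0.05), and the chi-square per degree of freedom between 2 libraries was 112.1, 107.6 and 87.4, so no pair was 1 library sequenced again. Pearson's r between libraries, across genes on the log2(CPM + 1) scale, was 0.752, 0.755 and 0.79, where genes are not independent replicates. In all, 1127 genes had 0 counts in at least 1 library and at least 50 in another, against 0 in a draw of pure counting error. The biological coefficient of variation estimated by edgeR was 0.832. The CV between replicates 1 and 2 fell from 126% for genes near 7.15 CPM to 21.5% for genes near 697 CPM. No gene was more variable than others of its level by edgeR's quasi-likelihood dispersion at an adjusted p under 0.05, limma called 0 as well, and the 477 genes at an unadjusted p under 0.05 are fewer than the share of 0.05 that chance gives. The edgeR test called 3 genes without replicate 1, 5 without replicate 2 and 2 without replicate 3. In simulated data of the same size, with all 3 libraries, that test recovered 52% of genes changed 16-fold in 1 library and 4% of those changed 4-fold.

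**Figure D3:**
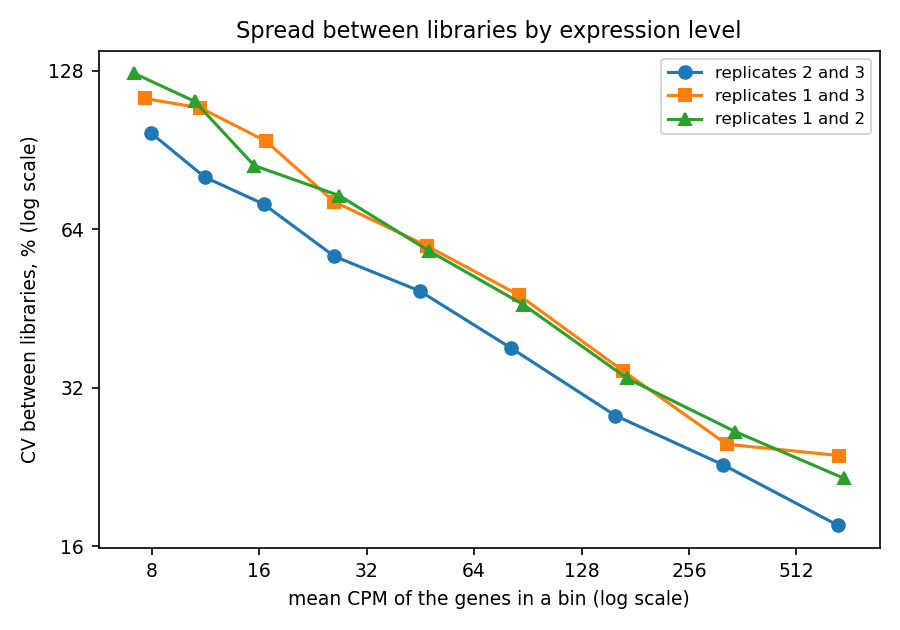
Coefficient of variation between pairs of libraries, in percent with counting error removed, against the mean CPM of the genes in a bin; both axes are logarithmic and bins were set by the third library. In each pair the CV falls as expression rises, from 126% to 21.5% for replicates 1 and 2.

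Most gene lists did not deviate in a single library beyond random lists. Of 72 combinations of 24 lists and 3 libraries, 2 had a median deviation below the 0.5th percentile of 10000 random lists matched on expression, or as far above, where 0.72 are expected by chance, so the count itself does not exclude chance. The inhibitory markers had a median deviation of -0.89 on the log2(CPM + 1) scale in replicate 2, where 5 of 6 members lay below their own mean, Gad1, Gad2, Slc32a1, Slc6a5 and Pax2. The same list stood at percentile 99.3 in replicate 3, with a median deviation of 0.57 and 5 of 6 members above their mean. Neuropeptide genes had a median deviation of -1.18 in replicate 1, where all 8 measured members lay below their mean. Sst had 282, 751 and 2263 counts and Cck 138, 506 and 1444, whereas Penk had 464, 526 and 609, and Npy (0, 138 and 1) and Nppc (0, 180 and 0) came almost wholly from replicate 2. Adcyap1, Vgf and Nts were the other members. Granule cell markers stood at percentile 0.78 in replicate 1, with a median deviation of -0.28, and at percentile 99.2 in replicate 3, with 0.24. Purkinje cell markers stood at percentiles 2.16 and 98.7 in the same libraries, unipolar brush cell markers at 2.15 and 98.2, and markers of molecular layer interneurons and Golgi cells at 10.75 and 96.2. The glutamatergic deep nuclei list stood at 87.8 in replicate 1 and 20.8 in replicate 3. Deviations are taken from each gene's mean over the 3 libraries, so a low standing in 1 library raises the others, and such pairs of percentiles are tied.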

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

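Reads assigned to no annotated feature are data that the gene comparisons do not use. They made up 50.2% of the reads assigned to a gene, to several genes or to no feature in replicate 1. The share was 44.1% in replicate 2 and 44.7% in replicate 3. Whether these reads lie outside genes, in introns or on the other strand cannot be told, since the counting settings are not given. Outliers within a group are not tested with 3 libraries, and with 1 group no effects were compared between groups.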

How the results depend on the processing

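The restriction of lists to members with a coding transcript of at least 2 kb and the placing of lists among random lists by RPKM were chosen after seeing the data; the others were planned. By RPKM 6 lists stood above the 95th percentile, as by CPM. The only difference that changed sign was Slc32a1 minus Slc6a5, which was 0.94 as RPKM and ranged from -0.75 to 0.16 when 1 library was left out; the cause was not tested. No other difference between lists or genes changed sign under any alternative, and those that moved by more than 1 SD follow. As RPKM, the pan-neuronal list exceeded oligodendrocyte, microglial and vascular markers by 2.40, 6.58 and 5.62, the glutamatergic deep nuclei list exceeded Hox genes by 1.80, Gad1 minus Gad2 was -0.59 and Htr6 minus Htr5a was -2.45. With a pseudocount of 0.1, the pan-neuronal list exceeded microglial and vascular markers by 9.89 and 6.29, the deep nuclei list exceeded Hox genes by 6.83, and Htr6 minus Htr5a was -7.02; all but the vascular value rest on genes at or near 0, where the pseudocount sets the value. Restricted to members of at least 2 kb, the pan-neuronal list exceeded oligodendrocyte, microglial and vascular markers by 0.87, 7.07 and 6.46, and the deep nuclei list minus the Purkinje list was -4.96. Among members with at least 10 counts summed, pan-neuronal minus microglial markers was 7.25 and deep nuclei minus granule cell markers -3.86. With means in place of medians, pan-neuronal minus vascular markers was 6.57. The count of genes beyond counting error was 6718 with at least 100 counts in 2 libraries, where fewer genes (6887) were tested. Genes more variable than their level numbered 20 with no filter and 2 to 5 when 1 library was left out, against 0. In all, 100 of the alternative values stayed within 1 SD or 1.5 times of the reported ones. No gene was in 2 lists, so the planned restriction to unshared members changed nothing and was not run, and no Hox gene of the list passed the filter of 10 counts. No paired analysis was possible because there is only 1 group. The spread between libraries, more than the read depth, limits what can be said of genes under about 50 CPM.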

Other observations

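The tests of transcript length and GC content among ribosomal protein genes took their present form after results for short transcripts in general and a first length result had been seen, and the test of near-identical copies was added after both; all 3 patterns were noticed in the same data. Immediate early genes, which neuronal activity and tissue stress induce, were uneven. The phosphatase gene Dusp1 was at 227 ± 29.7 CPM (SD, n = 3), Egr1 at 78.7 ± 30.3 CPM and Jun at 26.4 ± 4.1 CPM. Egr2 had 306, 68 and 0 counts and Nr4a1 13, 254 and 2, Fos had counts only in replicate 3 (6 counts), Npas4 and Ier2 had at most 1 count in a library, and Junb had none. The list of nuclear-retained and long noncoding RNAs was abundant, led by Malat1 and by Meg3 (1447 ± 234 CPM) and Snhg11 (972 ± 320 CPM). Rian was at 115 ± 30.1 CPM, and Neat1 and Miat were lower. The GENCODE annotation used here classes Snhg11 as protein-coding. Transcripts of both sexes were present in every library: Xist, transcribed in females, had 1556, 2543 and 1537 counts, and the Y-linked genes Ddx3y (149, 383 and 299 counts), Kdm5d (345, 116 and 125 counts), Uty (67, 249 and 258 counts) and Eif2s3y (98, 96 and 39 counts) were present in all 3. RNA of 1 mouse alone does not give both, so each library held RNA of more than 1 animal unless RNA or reads were carried over between libraries, which was not tested.

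The spread between libraries far beyond counting error (10773 of 11168 genes) was weighed against its possible causes. Different shares of cell types in the 3 dissections would make markers of a type move together. List means, however, held only 4.5% of the variance of 13 cell type lists beyond chance (-5.9 to 12.7 when set against the central 95% of random lists). This argues against such shares as the main cause of the variance pooled over these lists. Low markers varied most and so weigh most in it, such as Otx2 with an SD of 2.51 in log2 units, against 0.22 for Cbln3. The test therefore says little about abundant markers, and a part played by such shares stays open. Markers of granule, Purkinje and unipolar brush cells were all at low percentiles in replicate 1 (0.78, 2.16 and 2.15) and high ones in replicate 3. Inhibitory markers stood at 0.03 in replicate 2 and 99.3 in replicate 3. Since deviations are taken from a gene's own mean over the 3 libraries, a low value in 1 library raises the others. The low and high percentiles of a list are therefore not separate observations. The relative spread instead fell with abundance, with a slope of log2 squared CV on log2 CPM of -0.78 (95% bootstrap interval -0.80 to -0.75). Simulated libraries of few molecules gave -0.89 and a spread of the same relative size at every level gave -0.02, so the slope is consistent with few RNA molecules entering each library before amplification, as a hypothesis. Differences between animals stay open for single genes such as Oprm1, and no other biological explanation was tested.

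Htr6 near 0 in a line named for it is a second pattern. Another gene overlapping its exons, which would make its reads ambiguous, is argued against by the GENCODE annotation, in which 0.0% of its exonic bases lie in exons of another gene; the annotation used for the deposited counts is not given in the sources used here. A gene model of Htr6 in that annotation that leaves out part of its exons may therefore account for the low counts, and was not tested. The test of chance loss decides nothing for Htr6: of the genes at 10 to 20 CPM in 1 library, 2.8% (139 of 4986, exact 95% interval 2.3 to 3.3) had 1 count or fewer in both others, but Htr6 reached at most 0.794 CPM. A low level of the endogenous gene stays open too and was not tested.

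The cytosolic ribosomal protein genes, whose transcripts are usually among the most abundant, were also low. The 83 genes other than Rpl10a had a median of only 4.24 on the log2(CPM + 1) scale, against 3.58 for all genes with at least 10 counts summed. They were picked by symbol, which can take in like-named paralogs that need not be abundant. Among 76 of them without such paralogs, the shorter genes had a median CPM of 17.8, 13.1 and 12.1 in replicates 1, 2 and 3. The longer ones had 24.0, 27.1 and 21.9. Reads lost to near-identical copies would lower RPKM as the shared part of the transcript grows. Spearman's rho was 0.08 to 0.19 among the same 76 genes. Both measures are taken over transcript length, which can raise rho, so this correlation does not decide the question. The 71 genes with a copy had a median RPKM of 23.3, 19.6 and 17.7 in replicates 1, 2 and 3. The few without a copy were not higher, at 12.1, 15.1 and 15.4. A loss to copies stays open. Loss of short transcripts stays open. RPKM was related to length with rho from -0.22 to 0.12 over 3 libraries and 3 choices of transcript (CPM with rho from 0.347 to 0.382). However, 92.1% of the 76 transcripts are under 2 kb, so a loss would act on nearly all alike. Restriction to markers of at least 2 kb lowered the pan-neuronal minus oligodendrocyte and microglial differences to 0.87 and 7.07. It moved deep nuclei minus Purkinje markers from -2.39 to -4.96, raised the vascular difference to 6.46 and left the astrocyte one within its SD. The vascular rise does not speak against such a loss, since the pan-neuronal list lost Tubb3 (1868 bases), its lowest member. The Purkinje list lost low members such as Pcp4 (641 bases), but the deep nuclei list lost a high member, Spp1 (1507 bases). These shifts therefore do not settle the question. GC content stays open as well, with partial rho of -0.11 to -0.09 at fixed length over a narrow range (middle 50% of genes, 48.4 to 54.8% GC). These correlations are across genes, which are not independent replicates, and a low ribosome occupancy of these transcripts stays open and was not tested.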
